A study of Xenopus laevis with 12 samples.

How the data were processed

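Total RNA of animal caps was extracted with TRIzol and labelled with biotin by the 3' in vitro transcription method for the array, per the labels. Each of the 12 arrays stands for 1 sample, in 4 groups of 3 taken from the sample titles: lacZ, kctd15, wnt3a with chordin (wnt3a+chordin), and all 3 mRNAs (wnt3a+chordin+kctd15). The deposited values are log2 expression per probe set. The labels name Partek for processing, and its version, the background step, the summarisation and the normalization are not given in the sources used here. The log2 unit was checked on the values, which ran from 2.38 to 15.58 with none negative. The 75th percentiles of the arrays lay between 9.13 and 9.17, as after a normalization between arrays. For arrays without scanner files no depth can be given.

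Of 32635 probe sets, 96 Affymetrix controls and 64 reporters were left out of the tests, which leaves 32475. Of these 15495 had 1 gene symbol in the platform annotation, 279 had several and 16701 had none. Gene identifiers of 15384 probe sets were found in the annotation of the Xenopus laevis assembly 10.1, which gave current symbols and positions, and those of 111 were not. The 11303 symbols include separate entries for the homeologs of a gene, marked .L and .S, and 2702 genes had more than 1 probe set.

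All 12 arrays were fitted together with 4 group means in limma 3.58.1 (lmFit, contrasts.fit, eBayes) under R 4.3.3, and p values were two-sided and adjusted by the method of Benjamini and Hochberg over the tested probe sets, separately for each of 5 contrasts. Adjusted p under 0.05 was the threshold for a call. The contrasts were kctd15 minus lacZ, wnt3a+chordin minus lacZ, wnt3a+chordin+kctd15 minus wnt3a+chordin, wnt3a+chordin+kctd15 minus lacZ, and the interaction, which is the third minus the first. Replicate differences are differences between arrays with the same replicate number. These numbers appear in the sample titles, and what they mark is not given. Arrays with 1 number deviated together from their group means: the correlation of the deviations was 0.18 to 0.71 (median 0.50) over 18 pairs with the same number and -0.51 to 0.10 (median -0.25) over 36 pairs with different numbers, and in 36 of 36 comparisons an array matched its own number best. The fit with the replicate number as a block is therefore given wherever it changes the call of a list or of a named or injected gene, or moves the number of probe sets or of list members past the threshold by more than 1.5 times.

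Gene lists for 17 cell types and pathways were tested with camera in limma, with a preset correlation of 0.01, on 1 probe set per gene (the one with the highest mean). The p values were adjusted over all 85 tests of 17 lists in 5 contrasts. The lists were neural plate border, neural crest, neural plate (pan-neural), neuronal differentiation, anterior neural, posterior neural, cranial placode, non-neural ectoderm and epidermis, ionocyte with multiciliated and small secretory cells, cement and hatching gland, mesoderm, endoderm, blood and myeloid, Wnt targets, BMP targets, p53 and stress response, and cell cycle. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, were run beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone. Another 2 lists, somitic muscle and notochord with axial mesoderm, were added after the values were seen and were used only for levels per array. The groups, contrasts, tests, 17 lists, rule for named genes and most alternatives were fixed before the data were examined.

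Named genes were chosen by a rule. It takes the injected genes and, per comparison of 2 groups, up to 8 genes in each direction with the largest absolute log2 fold change among those past the threshold whose 3 arrays in 1 group all lie above the 3 of the other (for the interaction up to 5 in each direction without that condition). It also takes, per comparison and list, up to 4 members past the threshold with the largest absolute log2 fold change, or, where none passed, the member with the smallest p. Genes named beyond it are said to have been chosen after their values were seen. The rule left out symbols that are placeholders, to which symbols of XB followed by digits were added.

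Tests were run on simulated data with this number of arrays and the measured spread. Of probe sets simulated to change by 1 log2 unit, 50% to 56% were recovered in the comparisons of 2 groups and 32% in the interaction, and of those by 2 log2 units 85% to 93% and 73%, with 6 to 12 false calls per simulation. A simulated list shift of 1 log2 unit was found in 3 of 3 tests, with 2 calls among 82 others. This does not cover lists of correlated genes.

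Alternatives were the replicate block, quantile normalization, arrays centred on their medians, array weights, a variance prior with trend, dim probe sets left out (mean log2 at or below the median of all), 1 probe set per gene, only the arrays of the groups compared, adjusted p under 0.01, at least 1.5-fold, all probe sets of a listed gene, and each array left out in turn. Chosen after the data were seen were leaving out all arrays numbered 3, the muscle mean of each array as a covariate, and leaving out arrays for results other than the counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.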

Results

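Gene expression was measured on a 3' Affymetrix array in animal caps of Xenopus laevis, the ectoderm cut from the animal pole of the blastula, which forms epidermis unless other signals reach it. The 12 arrays fall into 4 groups of 3, by the mRNA injected into the embryo at the 2-cell stage: lacZ as control, kctd15, wnt3a with chordin, and wnt3a with chordin and kctd15. Caps were dissected at stage 9 and collected at stage 15. The series title gives the purpose as finding targets of Kctd15, a protein with a BTB domain that restricts neural crest formation, in caps turned towards neural crest by wnt3a, a Wnt ligand, and chordin, an antagonist of BMP ligands. Log2 values of the 32635 probe sets ran from 2.38 to 15.58 over the 12 arrays, with medians per array from 7.17 to 7.28, and the number of arrays limits the precision of every value. Replicates of a group correlated across probe sets at Pearson's r of 0.971 to 0.986. Arrays with and without wnt3a and chordin correlated at 0.842 to 0.918, and the first principal component, which parted them, held 69.4% of the variance. The labels do not say whether the 3 replicates came from separate batches of embryos, so the p values below measure only the spread among these samples. Values below are log2 fold changes with their standard errors (SE), n = 3 arrays per group, unless another unit is given.

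The levels of the injected genes were read first, as a check of the group labels. The probe set for wnt3a.S (chromosome 6S, 5150961 to 5209595, Xenopus laevis assembly 10.1) was at 12.76 ± 0.26 (SD, n = 3) with wnt3a+chordin and 12.59 ± 0.49 with kctd15 added, against 5.90 ± 0.63 with lacZ and 4.58 ± 0.61 with kctd15 alone. The probe set for chrd.1.S, chordin (5S, 86328071 to 86344435), was at 9.69 ± 1.04 and 9.62 ± 1.32 in the arrays with wnt3a and chordin, but at 5.75 ± 3.14 with lacZ and 6.26 ± 2.47 with kctd15. Replicate 3 of lacZ (9.37) and replicate 3 of kctd15 (9.08) were as high as the arrays with chordin mRNA, while the other 4 arrays without it lay between 3.79 and 5.23. Its difference between wnt3a+chordin and lacZ, 3.95, missed the threshold (limma, adjusted p = 0.0652). That difference passed with the replicate number as a block (adjusted p = 0.0293) and without lacZ replicate 3 (5.76, adjusted p = 0.00535). The 1 probe set for kctd15.L (Xl2.13377.1.A1_at, 4L, 61810114 to 61840321) went against the labels. It was lower, not higher, in the arrays labelled kctd15: 4.79 ± 1.43 against 10.96 ± 0.26 with lacZ, and 5.16 ± 1.63 against 10.66 ± 0.40 in the pair of groups with wnt3a and chordin. Where the probes lie relative to the injected kctd15 mRNA is not given. Below, kctd15 names groups by label alone, and each comparison of them rests on those labels.

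The array also carries 4 reporter probe sets for the lac operon. Reporter 2 was at 14.24 ± 0.32 with lacZ, 13.53 ± 0.54 with kctd15, 13.95 ± 0.44 with wnt3a+chordin and 4.96 ± 0.26 with all 3 mRNAs. The fall in the last group, in 3 of 3 arrays against wnt3a+chordin and against lacZ, had an exact two-sided permutation p = 0.1, the smallest that 3 arrays against 3 can give. The other reporters had group means between 3.75 and 6.68. The amounts of lacZ mRNA in the groups other than lacZ are not given in the sources used here.

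**Figure D1:**
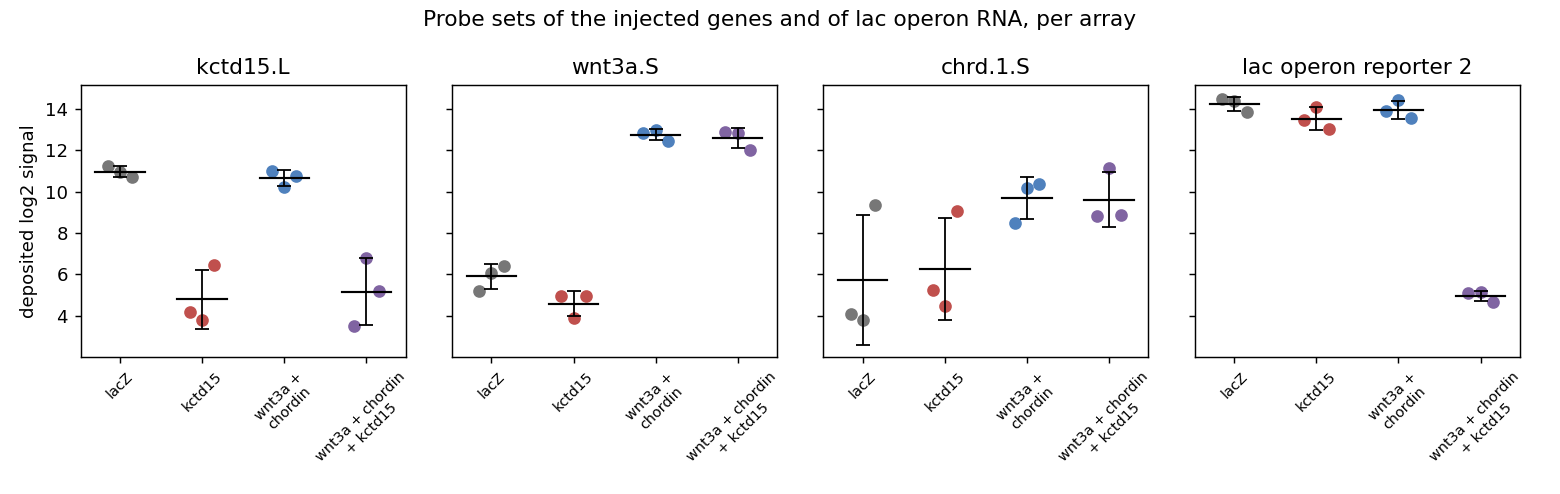
Deposited log2 level of the probe sets for kctd15.L, wnt3a.S and chrd.1.S and of lac operon reporter 2 in each of the 12 arrays (points), with group means (lines) and SD (bars). The 3 arrays of each group labelled kctd15 sit below every array without it for kctd15.L, at most 6.77 against at least 10.22.

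Transcripts of muscle and of axial mesoderm, which caps without inducers are known to lack, differed between replicates within groups. The mean over 19 somitic muscle members was 8.24 in lacZ replicate 3 against 5.13 and 4.96 in the other lacZ arrays, and 8.79 in replicate 2 of wnt3a+chordin+kctd15 against 5.26 and 6.49. In wnt3a+chordin it was 5.1, 7.59 and 7.52, and in kctd15 5.47, 5.23 and 6.37, for replicates 1, 2 and 3. The probe set for actc1.L, a sarcomeric actin, ran from 5.18 to 11.08 within lacZ and from 5.72 to 11.90 within wnt3a+chordin+kctd15. Of 10 notochord and axial mesoderm members, 9 were more than 1 log2 unit higher in lacZ replicate 3 than the mean of the other lacZ arrays, with a median difference of 2.51, and 9 in replicate 2 of wnt3a+chordin+kctd15, with a median of 3.37. Both lists were drawn up after the values were seen. In kctd15 replicate 3 the notochord and axial mesoderm members lay a median of 2.17 above the other kctd15 arrays, with 9 of 10 more than 1 log2 unit higher, and in replicate 1 of wnt3a+chordin a median of 2.57 below the others, with 9 of 10 more than 1 log2 unit lower. In replicate 1 of wnt3a+chordin+kctd15 the median was -2.21. In lacZ replicate 3 the pan-neural, anterior neural, mesoderm and cement gland lists lay above the mean of the other lacZ arrays by medians of 1.53, 1.15, 1.57 and 2.01, with 17 of 23, 12 of 21, 20 of 30 and 4 of 5 members more than 1 log2 unit higher. In replicate 2 of wnt3a+chordin+kctd15 the posterior neural, ionocyte and mesoderm lists lay above the others by medians of 1.40, 1.99 and 1.78. In replicate 1 the posterior neural list lay below the others, by medians of -1.87 in wnt3a+chordin and -1.48 in wnt3a+chordin+kctd15. In kctd15 replicate 3 the pan-neural list was higher by a median of 0.95, with 11 of 23 members more than 1 log2 unit higher.

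**Figure D2:**
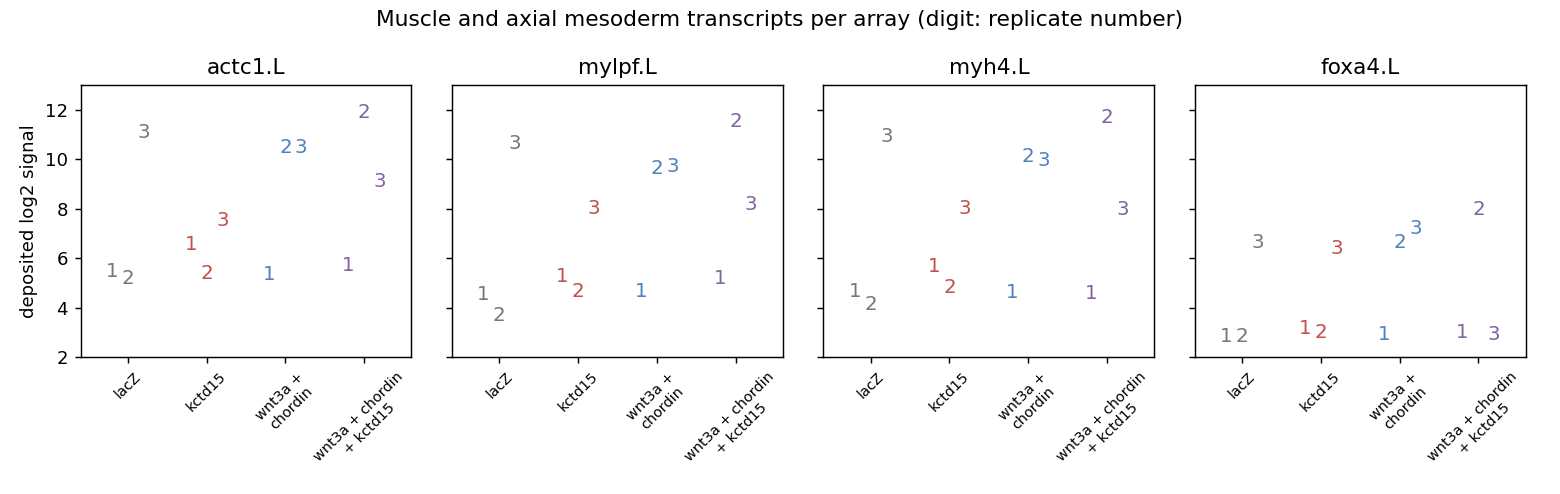
Deposited log2 level of actc1.L, mylpf.L and myh4.L, of muscle, and foxa4.L, of the notochord, in each of the 12 arrays, drawn as the replicate number in the colour of its group. Arrays of 1 group differ, as in lacZ, where actc1.L is at 11.08 in replicate 3 and at 5.47 and 5.18 in the others.

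The comparison of wnt3a+chordin with lacZ asks what these 2 mRNAs do to the caps. In the gene lists 17 of 21 neural crest, 19 of 23 pan-neural and 9 of 32 posterior neural members rose, and 16 of 23 epidermal and 26 of 27 ionocyte, multiciliated and small secretory cell members fell. foxd3.L, a transcription factor of early neural crest (4L, 79876430 to 79878140), rose by 7.17 (SE 0.67, adjusted p = 1.72e-05), from 4.54 ± 1.07 to 11.71 ± 0.47 (SD, n = 3). hoxa2.L, a hindbrain Hox gene (6L, 43384616 to 43386597), rose by 4.93 (SE 0.16, adjusted p = 3.87e-07). foxi1.L, the regulator of ionocytes (3L, 39080723 to 39082941), fell by 8.02 (SE 0.89, adjusted p = 5.18e-05), and szl.L, sizzled, a secreted BMP feedback regulator (3L, 78197199 to 78199645), fell by 9.08 (SE 1.05, adjusted p = 6.78e-05). In each of these the 3 arrays of 1 group lay above the 3 of the other. Among the largest increases were also xa-1.L (8.14), aqp3.L (7.55), a water and glycerol channel, cyp26c1.S (7.46), which breaks down retinoic acid, pax3.L (7.02) and zic1.S (6.72). The largest decreases included val.L (-9.48), tekt2.S (-8.24) and odf3.S (-8.23), which are parts of cilia and flagella, tbc1d24.2.L (-8.21), slc26a4l.L (-8.18), an anion exchanger, and atp6v1g3.L (-7.87), a proton pump subunit.

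In the neural crest list, 17 of 21 measured members rose (18 adjusted over the list alone) and 4 did not pass, with a median of 3.43. foxd3.S (6.90), sox9.S (5.69) and sox10.L (5.18) were among them. The list shifted up in 3 of 3 replicate differences (camera, adjusted p = 9.19e-06; adjusted p = 0.345 with an estimated correlation). Of 20 neural plate border members, 12 rose and 1, dlx5.L (-1.09), fell, the same counts adjusted over the list alone. pax3.S (6.36), znf703.S (3.63) and dlx6.L (2.49) rose, and the list shifted up with a median of 1.19 (adjusted p = 0.00547; adjusted p = 0.530 with an estimated correlation). One listed gene, pax3.L, had probe sets past the threshold in both directions. Of the 23 members of the pan-neural list, 19 rose (19 adjusted over the list alone), with a median of 3.26, among them zic2.L (5.36), zeb2.S (4.58) and ncam1.S (4.18), a neural cell adhesion molecule. Its shift gave adjusted p = 8.02e-06, and adjusted p = 0.530 with an estimated correlation. The pan-neural replicate medians were 3.26, 3.65 and 1.80, the last against lacZ replicate 3, in which these genes lay a median of 1.53 above the other lacZ arrays. Neuronal differentiation genes followed, with 15 of 23 higher and 1 lower (17 and 1 adjusted over the list alone). tubb2b.S, a neural tubulin, rose by 4.76 and elavl3.L by 3.38, while isl1.S fell by 3.16. That list shifted up by a median of 1.05 (adjusted p = 0.00211; adjusted p = 0.530 with an estimated correlation), and lost the call when dim probe sets were left out (adjusted p = 0.246). In 3 of 3 replicate differences the medians of these 3 lists were above 0.

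Posterior neural genes rose in 9 of 32 members (9 adjusted over the list alone), led by hoxb2.S (6.66), hoxa2.S (4.71) and hoxb4.S (2.62). The list median was 0.83, with replicate differences of 0.14, 1.66 and 1.27 (adjusted p = 0.0105; adjusted p = 0.654 with an estimated correlation). These replicates also differ in the muscle mean given above. Anterior neural genes were not called as a list (median -0.30, adjusted p = 0.122). Their replicate medians were -0.02, 0.07 and -1.14, the last against lacZ replicate 3, where they lay a median of 1.15 above the other lacZ arrays, and the list shifted down without lacZ replicate 1 (adjusted p = 0.0376) or 2 (0.0407). Of 21 anterior genes pax6.L rose (2.35, adjusted p = 0.048; 0.0509 with the block) and six3.L, hesx1.L and emx2.L fell (-2.24, -1.47 and -1.29), against 0 higher and 2 lower adjusted over the list alone. In the cranial placode list, cyp26c1.S and pax2.L (1.80) rose among 11 (1 adjusted over the list alone; 2 higher and 2 lower with the block). That list had a median of -0.03 and a mean of 0.68, and the test pointed down (adjusted p = 0.913).

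The ionocyte, multiciliated and small secretory cell list fell almost whole: 26 of 27 members were lower (26 adjusted over the list alone), with a median of -5.02. atp6v1b1.L, a proton pump subunit of ionocytes, fell by 7.50. Replicate medians were -5.49, -4.77 and -5.07 (adjusted p = 2.47e-15; adjusted p = 0.345 with an estimated correlation). Of 23 epidermal genes, 16 fell and 1, epcam.S (0.53), rose (16 and 1 adjusted over the list alone). itln1.L, intelectin, a secreted lectin, fell (-6.51), as did the regulator gata3.S (-5.88) and the keratin krt12.4.S (-5.87). The epidermal median was -2.61, below 0 in 3 of 3 replicate differences (adjusted p = 1.36e-06; adjusted p = 0.373 with an estimated correlation). In the list of cement and hatching gland genes, 3 of 5 fell (3 adjusted over the list alone): agr2.L (-7.19), agr2.S (-6.46) and ag1.S (-2.58). Its shift was downward in 3 of 3 (median -2.58, adjusted p = 0.00902; adjusted p = 0.499 with an estimated correlation), and the call was lost without all arrays numbered 3 (adjusted p = 0.065). Cement gland replicate medians were -1.03, -2.96 and -3.94, the last against lacZ replicate 3, where 4 of 5 members were more than 1 log2 unit higher than in the other lacZ arrays.

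Wnt target genes rose in 12 of 32 members (12 adjusted over the list alone), including sp5.L (4.85), axin2.S (4.11), a negative regulator of the pathway, and tcf7.S (3.97). The median was 0.75, above 0 in 3 of 3 (adjusted p = 0.0018; adjusted p = 0.345 with an estimated correlation). BMP target genes fell in 25 of 33 members and rose in 4 (25 and 5 adjusted over the list alone), with a median of -2.44 below 0 in 3 of 3 (adjusted p = 1.36e-08; adjusted p = 0.345 with an estimated correlation). szl.S (-7.58) and tbx3.S (-6.90) fell. The 4 that rose, looked up after the values were seen, were msx1.S (1.88), msx1.L (1.54), msx2.L (0.98) and id3.S (0.32), of which the msx genes also mark the neural plate border. Cell cycle genes rose in 17 of 28 (17 adjusted over the list alone), such as mcm5.L (1.82) and pcna.S (1.70), both of DNA replication (median 0.68, above 0 in 3 of 3, adjusted p = 0.00101; adjusted p = 0.485 with an estimated correlation). No shift was called for mesoderm, endoderm, blood or p53 genes (adjusted p = 0.562, 0.187, 0.553 and 0.997). Of 30 mesoderm genes, wnt8a.L rose (2.68) and nkx2-5.S, foxc1.L and mespb.L fell (-3.86, -1.32 and -0.89), against 1 higher and 2 lower adjusted over the list alone. The mesoderm median (0.07) and mean (0.10) were above 0 while the test pointed down. Of 18 endoderm genes, cer1.S (3.02) and foxa2.L (1.21) rose and hhex.L (-4.42), gata6.L (-2.14), gata5.S (-1.09) and gata5.L (-1.09) fell, with the same counts adjusted over the list alone. Of 17 blood genes, spib.L (0.76) rose and cebpa.L (-3.68) and hba3.L (-1.14) fell, also 1 and 2 adjusted over the list alone. In the p53 and stress list, 3 of 21 rose, sesn1.L (2.17), ddit3.L (1.65) and atf3.L (0.59), and 2 fell, gadd45a.S (-2.06) and cdkn1a.L (-1.22), the same counts adjusted over the list alone.

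In all, 13421 of 32475 probe sets changed between wnt3a+chordin and lacZ (limma, adjusted p under 0.05), 7855 higher and 5566 lower, and 2836 and 3656 of them by 2-fold or more. Of 71 named genes 64 kept the call with each array left out in turn. The other 7 were hesx1.L, foxa2.L, cdkn1a.L, mespb.L, pax2.L, ag1.S and pax6.L, with highest adjusted p from 0.07 to 0.171.

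**Figure D3:**
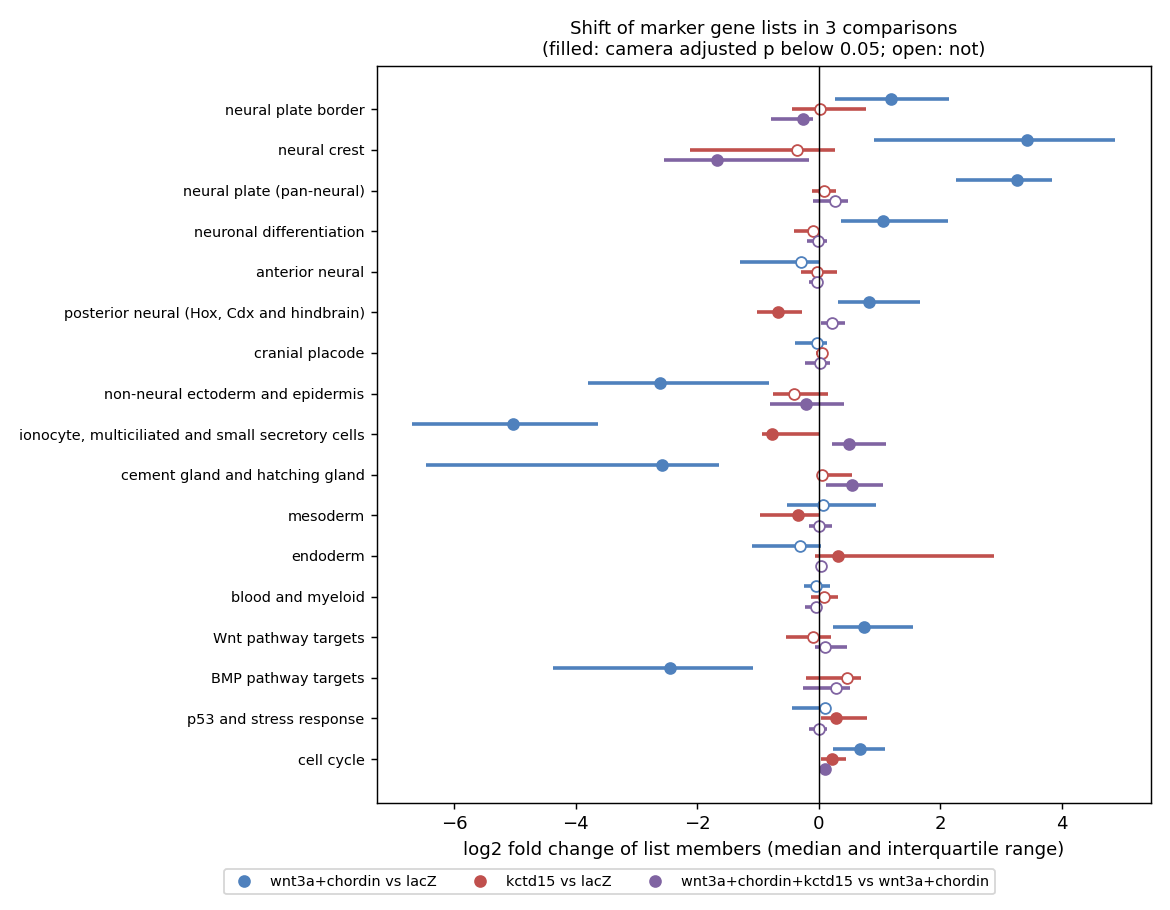
Median log2 fold change (point) and interquartile range (bar) of the measured members of each of the 17 gene lists in 3 comparisons, filled where camera called the list with its preset correlation. The median of the neural crest list is 3.43 in wnt3a+chordin against lacZ and -1.68 in wnt3a+chordin+kctd15 against wnt3a+chordin.

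The comparison of wnt3a+chordin+kctd15 with wnt3a+chordin addresses the question in the series title, the genes that respond to Kctd15. The arrays also differ in kctd15.L (-5.5, SE 0.80, adjusted p = 0.0156), against the label, and in reporter 2 (-8.99). snai2.L, which governs the exit of crest cells from the epithelium (6L, 121146981 to 121151491), fell by 4.36 (SE 0.81, adjusted p = 0.0457), from 11.10 ± 0.76 to 6.74 ± 2.04 (SD, n = 3). sox9.S (9_10S, 19840590 to 19846183), a crest and cartilage regulator, fell by 3.82 (SE 0.68, adjusted p = 0.0369) and sox9.L (9_10L, 21853266 to 21875574) by 2.64 (SE 0.43, adjusted p = 0.0239). tat.S, which encodes tyrosine aminotransferase (4S, 41700028 to 41732337), rose by 2.91 (SE 0.18, adjusted p = 0.000332). nodal3.1.L, a Nodal-related ligand of the organizer (3L, 141478446 to 141480825), rose by 4.58 (SE 0.76, adjusted p = 0.0263), from 5.76 ± 0.36 to 10.34 ± 2.06.

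In the neural crest list, 5 of 21 members fell (12 adjusted over the list alone), 16 did not pass, and the median was -1.68. ets1.L fell by 2.64 (adjusted p = 0.0399), and ednra.S, an endothelin receptor named after its value was seen, by 1.68 (SE 0.21, adjusted p = 0.00698). Replicate medians were -1.97, -1.74 and -0.73, the last with wnt3a+chordin+kctd15 replicate 3, where crest members lay a median of 1.08 above the other arrays of the group, and the list shifted down (camera, adjusted p = 2.19e-14; adjusted p = 0.230 with an estimated correlation), a call that held with each array left out in turn. Single crest genes were less firm. Without wnt3a+chordin replicate 1 the adjusted p of snai2.L was 0.188, of ets1.L 0.178 and of sox9.L 0.107, and without wnt3a+chordin+kctd15 replicate 1 that of sox9.S was 0.161. The call of ets1.L was also lost with the replicate block (adjusted p = 0.0532). In the neural plate border list, dlx6.L (-3.5, adjusted p = 0.0161) and dlx5.L (-1.56, adjusted p = 0.0121), homeobox genes of the border and the ventral ectoderm, fell among 20 members (5 adjusted over the list alone). The border list shifted down in 3 of 3 replicate differences (median -0.26, adjusted p = 6.51e-07; adjusted p = 0.345 with an estimated correlation), with each array left out as well. By fry it missed (adjusted p = 0.0868).

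Epidermal genes fell in 3 of 23 (4 adjusted over the list alone): tp63.L (-2.89, adjusted p = 0.0178) and tp63.S (-2.53, adjusted p = 0.0137), the regulator of the basal epidermis, and dlx3.L (-1.51, adjusted p = 0.014). That list shifted down by a median of -0.21, below 0 in 2 of 3 replicate differences (adjusted p = 0.00649; adjusted p = 0.563 with an estimated correlation). The call was lost without wnt3a+chordin replicate 1 (adjusted p = 0.229) or 3 (0.0985) or without wnt3a+chordin+kctd15 replicate 1 (0.388). The ionocyte list shifted up with a median of 0.49 (adjusted p = 1.88e-05; adjusted p = 0.530 with an estimated correlation), though 0 of its 27 members passed in limma, alone or with the block, or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The largest evidence was for atp6v1g3.L (2.61, adjusted p = 0.195). Its replicate medians were 0.02, 1.51 and -0.02, and without replicate 2 of wnt3a+chordin+kctd15, the array with the highest muscle mean, the call was lost (adjusted p = 0.566). Cement gland genes shifted up (median 0.55, replicate medians -0.12, 0.94 and 0.83, adjusted p = 0.0293; adjusted p = 0.530 with an estimated correlation). Of 5, 0 passed in limma over all probe sets and 1 adjusted over the list alone, agr2.S (1.72, adjusted p = 0.0651, and 0.0151 with the block). That 1 member was also the only 1 with an unadjusted p under 0.05. The cement gland call was lost with the block (adjusted p = 0.0504) and without any of 4 arrays, wnt3a+chordin+kctd15 replicates 1 (0.103) and 3 (0.0839) and wnt3a+chordin replicates 2 (0.203) and 3 (0.0703), as well as without all arrays numbered 3 (0.272). Cell cycle genes shifted up by a median of 0.10, above 0 in 3 of 3 (adjusted p = 0.00883; adjusted p = 0.530 with an estimated correlation), with 0 of 28 past the threshold in limma, alone or with the block, or adjusted over the list alone, and 1 at an unadjusted p under 0.05. The member with the smallest p was ccna2.L (0.53, adjusted p = 0.338), and the call was lost without wnt3a+chordin+kctd15 replicate 1 (adjusted p = 0.168). By fry the epidermal, ionocyte, cement gland and cell cycle lists all missed (adjusted p = 0.383, 0.352, 0.287 and 0.245).

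No shift was called in the other 11 lists. Neural plate genes (median 0.26, adjusted p = 0.17), anterior neural (-0.03, 0.65), posterior neural (0.22, 0.122), placode (0.03, 0.913), mesoderm (0.01, 0.997), endoderm (0.04, 0.673) and p53 genes (-0.00, 0.722) had 0 members past the threshold in limma. At an unadjusted p under 0.05 they had 1 higher, 0, 1 higher, 0, 1 higher, 1 higher with 1 lower, and 1 higher with 2 lower. With the block, 1 mesoderm gene passed, lhx1.L (1.82, adjusted p = 0.289 without it and 0.0215 with it), and 1 endoderm gene, gata6.L (1.46, adjusted p = 0.104 and 0.0343). Adjusted over the list alone, 1 endoderm member was higher and 1 lower, and 0 members of the others in this group. The mesoderm list shifted down without wnt3a+chordin replicate 1 (adjusted p = 0.0263) or wnt3a+chordin+kctd15 replicate 2 (0.0172), the arrays with the lowest and the highest muscle mean of these 6. The posterior list shifted up without wnt3a+chordin+kctd15 replicate 1 (5.14e-05) or wnt3a+chordin replicates 2 (0.00706) or 3 (0.0154), and the pan-neural list without all arrays numbered 3 (0.00125) or wnt3a+chordin replicate 2 (0.0495) or with all probe sets (0.0435). Neuronal genes had 1 of 23 lower, tlx3.S (-0.91, adjusted p = 0.0185), and 1 adjusted over the list alone (median -0.01, adjusted p = 0.213), and the list shifted down without wnt3a+chordin replicate 1 (0.00489). Blood genes had 1 of 17 lower, hbg1.L, a globin (-1.72, adjusted p = 0.0274), and 1 adjusted over the list alone (median -0.04, adjusted p = 0.365), and the list shifted down with all probe sets (0.0395) or with dim ones left out (0.00571). Wnt targets had 1 of 32 higher, nodal3.1.L, and 1 adjusted over the list alone (median 0.10, adjusted p = 0.112). BMP targets had 2 of 33 lower, dlx5.L and dlx3.L (1 higher and 3 lower adjusted over the list alone). The BMP median (0.29) and mean (0.14) were above 0 and the test pointed down (adjusted p = 0.969).

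Outside the lists, atp12a.L, a proton and potassium pump (3.23, adjusted p = 0.0138), kit.L, a receptor tyrosine kinase (2.14, 0.0149), hpgds.L (2.11, 0.0273), kalrn.L (1.88, 0.0114), naalad2.L (1.82, 0.0184) and sytl5.L (1.77, 0.0213) rose. crisp1.5.S (-4.87, 0.00785), aqp3.L (-4.34, 0.025), cib2.S, a calcium-binding protein (-3.98, 0.00284), and cav1.L, caveolin (-3.48, 0.034), fell. In each of these genes all 3 arrays of 1 group lay above the 3 of the other. In all, 210 of 32475 probe sets changed (limma, adjusted p under 0.05), 46 higher and 164 lower, and 33 and 139 of them by 2-fold or more. With the replicate block the count was 443, 152 higher and 291 lower, with 208 in common. Of 24 named genes past the threshold, tat.S, cib2.S and crisp1.5.S kept the call with each array left out, and the other 21 had highest adjusted p from 0.0526 (kalrn.L) to 0.188 (snai2.L). The count fell to 70 without wnt3a+chordin replicate 1, 67 without its replicate 3, 75 without wnt3a+chordin+kctd15 replicate 1 and 120 without its replicate 3, and to 6, 5 of them among the 210, without all arrays numbered 3.

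The comparison of kctd15 with lacZ asks how arrays labelled kctd15 differ from control without wnt3a and chordin, again on labels that the kctd15.L probe set (-6.17, SE 0.80, adjusted p = 0.00142) goes against. Of 10 gata genes, a family with regulators of endoderm and heart formation grouped after the values were seen, 5 were higher. gata5.S (9_10S, 13236806 to 13269758) rose by 5.17, which is 36-fold (SE 0.28, adjusted p = 1.5e-05), from 5.97 ± 0.59 to 11.14 ± 0.43 (SD, n = 3), and gata6.L (6L, 115719118 to 115744533) by 3.24 (SE 0.33, adjusted p = 0.000448). pck1.L, an enzyme of glucose synthesis (9_10L, 14042389 to 14047901), rose by 4.72 (SE 0.35, adjusted p = 9.61e-05) and klf2.S, a Kruppel-like factor (1S, 104915883 to 104919427), by 4.07 (SE 0.21, adjusted p = 1.44e-05). tp63.S, the regulator of basal epidermis (5S, 89257441 to 89347165), fell by 4.06 (SE 0.35, adjusted p = 0.000225).

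Among the largest increases were also irf1.L, an interferon regulatory factor (4.26), gata6.S (3.64), prkca.L, a protein kinase C (3.64), spam1.L, a hyaluronidase (3.6), and krt19.S, a keratin (3.5, and 2.55 in another probe set). The largest decreases included olfm4.L (-5.79), cldn1.S, a tight junction claudin (-5.37), mmp3.L, a matrix metalloproteinase (-4.92), bcam.L, a cell adhesion molecule (-4.71), cav1.L (-4.48) and nkx2-3.S, a homeobox gene (-4.11). For each of them all 3 arrays of 1 group lay above the 3 of the other, and adjusted p ran from 0.000137 to 0.00723.

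Of 18 endoderm genes 6 rose (6 adjusted over the list alone) and 12 did not pass. They were gata5.S, gata5.L (2.65), gata6.S, gata6.L, gata4.S (2.98) and hhex.L (3.13), and gata4.S and gata5.L were named after their values were seen. The list shifted up in 3 of 3 replicate differences, with a median of 0.32 and a mean of 1.2 (camera, adjusted p = 0.000476; adjusted p = 0.345 with an estimated correlation). When dim probe sets were left out the call was lost (adjusted p = 0.308). Neural crest genes fell in 4 of 21 (3 higher and 6 lower adjusted over the list alone): snai1.S (-3.61, adjusted p = 0.00288), sox8.L (-2.62, 0.0128), ednra.S (-2.56, 0.000137) and ets1.L (-2.25, 0.0186). The crest list as a whole missed the threshold (median -0.36, adjusted p = 0.0529), and passed without lacZ replicate 1 (0.0197) or 2 (0.0411) or with all probe sets (0.0028). Of 20 border genes dlx5.L (1.14), msx1.L (0.92) and csrnp1.L (0.73) rose and hes4.L fell (-1.35), with 4 higher and 3 lower adjusted over the list alone (median 0.02, adjusted p = 0.616).

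Posterior neural genes fell in 3 of 32 (3 adjusted over the list alone): evx1.L (-1.97), meis3.L (-1.60) and meis3.S (-0.97), cofactors or markers of hindbrain and trunk. The list shifted down in 3 of 3 (median -0.67, adjusted p = 0.00254; adjusted p = 0.585 with an estimated correlation), and missed by fry (adjusted p = 0.327). Ionocyte, multiciliated and secretory cell genes fell in 4 of 27 (4 adjusted over the list alone): foxa1.L (-3.06), tekt3.S (-2.80), tekt3.L (-2.16) and ift172.L (-0.80), of which the last 3 belong to cilia. This list also shifted down in 3 of 3 (median -0.77, adjusted p = 0.000384; adjusted p = 0.590 with an estimated correlation), but not by fry (adjusted p = 0.326) or with dim probe sets left out (0.09). In the mesoderm list foxc1.L (-2.10) fell among 30 (1 adjusted over the list alone, 3 with the block). Its replicate medians were -0.01, -0.02 and -1.29, so the downward shift (median -0.35, adjusted p = 0.018; adjusted p = 0.712 with an estimated correlation) came with lacZ replicate 3, the lacZ array with the higher muscle mean. The mesoderm call was lost without lacZ replicate 3 (adjusted p = 0.611), kctd15 replicate 1 (0.0642) or all arrays numbered 3 (0.154), with dim probe sets left out (0.5) and by fry (0.521).

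In the p53 and stress list 5 of 21 rose (5 adjusted over the list alone): gadd45g.L (1.60), gadd45g.S (1.55), jun.L (1.05), gadd45a.S (1.00) and sesn1.L (0.91), the last named after its value was seen. The shift was upward in 3 of 3 (median 0.28, adjusted p = 0.0244; adjusted p = 0.530 with an estimated correlation), and was lost without lacZ replicate 2 (0.0507), kctd15 replicate 3 (0.0584) or all arrays numbered 3 (0.0596). Cell cycle genes rose in 3 of 28 (11 with the block, and 9 higher and 1 lower adjusted over the list alone), ccne2.L (1.34), ccna2.S (0.68) and ccne1.L (0.55), which are cyclins. That list shifted up in 3 of 3 (median 0.22, adjusted p = 0.014; adjusted p = 0.530 with an estimated correlation), except without lacZ replicate 2 (0.0753). Epidermal genes went both ways among 23: tp63.S and tp63.L (-3.83) fell and the keratins krt12.2.L (3.07) and krt19.S rose, also 2 and 2 adjusted over the list alone (median -0.40, adjusted p = 0.14). BMP targets rose in 5 of 33, id4.S (1.74), tbx2.S (1.5), dlx5.L, msx1.L and id2.S (0.70), and fell in 2, tbx3.L (-2.14) and ventx1.1.S (-1.21), or 6 and 4 adjusted over the list alone (median 0.47, adjusted p = 0.122, and 0.0301 upward without lacZ replicate 2). Among Wnt targets dkk1.S (1.67) rose and axin2.L (-1.45) and znrf3.S (-0.65) fell, as adjusted over the list alone (32 measured, median -0.10, adjusted p = 0.267, and 0.0465 downward without lacZ replicate 1). Neuronal genes had dll1.L, a Notch ligand (2.65), higher and isl1.S (-2.08) and myt1.S (-1.65) lower, as adjusted over the list alone (23 measured, median -0.10, adjusted p = 0.122, and 0.0308 and 0.0301 downward without lacZ replicates 1 and 2). In each remaining list 1 gene changed, also adjusted over the list alone: gmnn.L (1.16) of 23 pan-neural, emx2.L (-1.40) of 21 anterior neural, pitx3.S (1.09) of 11 placode, agr2.S (1.43) of 5 cement gland and runx1.L (1.74) of 17 blood genes. With the block 2 pan-neural (1 higher and 1 lower) and 2 blood genes passed. The tests of these lists gave, in that order, adjusted p = 0.972, 0.507, 0.584, 0.565 and 0.466, with medians of 0.08, -0.03, 0.06, 0.06 and 0.09. The pan-neural mean (-0.00) and test pointed down and its median up, and the anterior mean (0.04) was up while its median and test were down. Pan-neural replicate medians were 0.44, 0.23 and -0.55, and without lacZ replicate 3, in which these genes were higher, the list shifted up (adjusted p = 0.00246).

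In all, 2269 of 32475 probe sets changed between kctd15 and lacZ (limma, adjusted p under 0.05), 869 higher and 1400 lower, and 419 and 869 by 2-fold or more. With the replicate block the count was 4992, 2479 higher and 2513 lower, and held all 2269. Of 58 named genes past the threshold 37 kept the call with each array left out, and the other 21, with highest adjusted p from 0.0507 (tbx3.L) to 0.168 (ventx1.1.S), included sox8.L (0.0522) and ets1.L (0.0751). The count was 1386 and 1367 without lacZ replicates 1 and 2, 1312 and 1355 without kctd15 replicates 1 and 2, and 1379, with 1167 shared, without all arrays numbered 3.

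The comparison of wnt3a+chordin+kctd15 with lacZ asks how far the caps with all 3 mRNAs stood from control. In these arrays kctd15.L was lower by 5.80 (SE 0.80, adjusted p = 0.000218) against the label, and reporter 2 differed by -9.28. zic1.S, a regulator of the neural plate border, rose by 7.04 (SE 0.74, adjusted p = 4.01e-05) from 6.43 ± 1.83 to 13.47 ± 0.30 (SD, n = 3), and hoxb2.S by 6.30 (SE 0.32, adjusted p = 1.98e-06). foxd3.L rose by 4.78 (SE 0.66, adjusted p = 0.00023), and val.L fell by 7.57 (SE 0.96, adjusted p = 0.00013). Also among the largest increases were cyp26c1.S (7.03), xa-1.L (6.98), pax3.L (6.73), fst.L, the activin antagonist follistatin (6.37), and tmem221.S (6.26), and among the largest decreases szl.L (-6.92), odf3.S (-6.73), tbc1d24.2.L (-6.67), tekt2.S (-6.52) and elovl2.L (-6.36). In each of them the 3 arrays of 1 group lay above the 3 of the other.

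Neural crest genes rose in 10 of 21 and fell in 1, ets1.L (-2.54), the same adjusted over the list alone. mycn.L (5.32), mycn.S (5.01) and foxd3.S (4.40) were among them, and the list shifted up in 3 of 3 replicate differences (median 1.53, camera, adjusted p = 0.0145; adjusted p = 0.530 with an estimated correlation). Pan-neural genes rose in 19 of 23 (19 adjusted over the list alone), including zic2.L (5.46), zeb2.S (5.09) and irx3.L (4.55), with a median of 3.21 and replicate medians of 4.35, 3.82 and 1.82, the last against lacZ replicate 3 (adjusted p = 2.79e-06; adjusted p = 0.530 with an estimated correlation). Neuronal genes rose in 14 of 23 and fell in 1, isl1.S (-3.16), or 16 and 1 adjusted over the list alone, with tubb2b.S (4.77) and elavl3.L (3.15) higher (median 1.1, adjusted p = 0.00681; adjusted p = 0.530 with an estimated correlation), and lost the call with dim probe sets left out (0.195). Posterior neural genes rose in 11 of 32 (11 adjusted over the list alone), such as hoxa2.L (5.00) and hoxb4.S (3.86). The posterior median was 0.96, with replicate medians of 0.06, 2.34 and 0.86, of which the highest was in the array with the most muscle transcripts (adjusted p = 0.00242; adjusted p = 0.585 with an estimated correlation). Wnt targets rose in 15 of 32 (16 higher and 1 lower adjusted over the list alone), among them sp5.L (5.31), nodal3.1.L (5.16) and axin2.S (4.13), with a median of 1.13 above 0 in 3 of 3 (adjusted p = 0.000476; adjusted p = 0.345 with an estimated correlation). Cell cycle genes rose in 19 of 28 (20 adjusted over the list alone), such as mcm5.L (1.88) and pcna.S (1.82), with a median of 0.74 above 0 in 3 of 3 (adjusted p = 4.14e-05; adjusted p = 0.345 with an estimated correlation).

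Ionocyte, multiciliated and secretory cell genes fell in 26 of 27 (26 adjusted over the list alone), with atp6v1b1.L (-6.20) and ccno.L, a regulator of multiciliated cells (-5.86), among them. Their replicate medians were -5.15, -3.25 and -5.20, the second from the array with the most muscle transcripts (median -4.59, adjusted p = 4.12e-14; adjusted p = 0.345 with an estimated correlation). Epidermal genes fell in 16 of 23 (18 adjusted over the list alone), such as gata2.L (-5.57) and grhl3.S (-4.67), with a median of -3.56 below 0 in 3 of 3 (adjusted p = 6.17e-08; adjusted p = 0.345 with an estimated correlation). BMP targets fell in 25 of 33 and rose in 3 (25 and 4 adjusted over the list alone), with szl.S (-6.27) and tbx3.S (-5.85) lower and msx1.S (1.64), msx1.L (1.39) and msx2.L (0.72), named after their values were seen, higher. Their median was -2.65, below 0 in 3 of 3 (adjusted p = 1.51e-08; adjusted p = 0.345 with an estimated correlation). In the cement gland list agr2.L (-6.14) and agr2.S (-4.74) fell among 5 (2 adjusted over the list alone), and the list shifted down in 3 of 3 (median -2.03, adjusted p = 0.0158; adjusted p = 0.530 with an estimated correlation) except without all arrays numbered 3 (0.065), with replicate medians of -1.15, -2.02 and -4.07, the last against lacZ replicate 3.

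No shift was called in the other 7 lists. Border genes rose in 8 of 20 and fell in 1, dlx5.L (-2.65), as adjusted over the list alone (median 0.49, adjusted p = 0.207, and 0.0344 upward without wnt3a+chordin+kctd15 replicate 2), with pax3.S (6.12) and znf703.S (3.48) higher. Of 21 anterior genes pax6.L (2.69) rose and six3.L (-2.42), hesx1.L (-1.63) and emx2.L (-1.03) fell, against 0 and 3 adjusted over the list alone (median -0.34, adjusted p = 0.0944). Anterior replicate medians were 0.06, -0.20 and -0.91, and the list shifted down without lacZ replicate 1 (0.026) or 2 (0.0296). Of 11 placode genes cyp26c1.S rose and foxi2.L (-0.80) fell, as adjusted over the list alone, and 2 rose and 2 fell with the block (median 0.08, adjusted p = 0.978). Of 30 mesoderm genes lhx1.L (3.06) rose and nkx2-5.S (-4.0) and foxc1.L (-1.30) fell, as adjusted over the list alone, and the median (0.02) and mean (0.13) were above 0 while the test pointed down (adjusted p = 0.594). Of 18 endoderm genes cer1.S (3.33) and mixer.L (0.35, named after its value was seen) rose and hhex.L (-4.27), gata5.L (-1.24) and gata5.S (-0.96) fell, or 1 and 3 adjusted over the list alone (median -0.22, adjusted p = 0.232). Of 17 blood genes spib.L (0.50) rose and cebpa.L (-3.01), hbg1.L (-1.77) and hba3.L (-1.18) fell, or 0 and 3 adjusted over the list alone (median -0.10, adjusted p = 0.331). In the p53 list 4 of 21 rose and 2 fell, as adjusted over the list alone (6 and 4 with the block), with sesn1.L (2.25) and ddit3.L (1.49) higher and cdkn1a.L (-2.11) and gadd45a.S (-1.24) lower (median -0.07, adjusted p = 0.913).

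In all, 13619 probe sets changed between wnt3a+chordin+kctd15 and lacZ (limma, adjusted p under 0.05), 7905 higher and 5714 lower, and 2866 and 3727 by 2-fold or more. Of 72 named genes 67 kept the call with each array left out, and the other 5, gata5.S, foxi2.L, krt12.4.S, pax6.L and spib.L, had highest adjusted p from 0.0542 to 0.137.

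The interaction tests whether the difference between arrays labelled kctd15 and their controls was itself different with and without wnt3a and chordin. kctd15.L itself had a difference of 0.66 (SE 1.13, adjusted p = 0.942), and reporter 2 one of -8.28. The rise of gata5.S and gata5.L in the arrays labelled kctd15 was smaller with wnt3a and chordin, while gata4.S, gata6.S and gata6.L did not pass: gata5.S differed by -5.04 (SE 0.39, adjusted p = 0.000852) and gata5.L (9_10L, 14594386 to 14625800) by -2.79 (SE 0.41, adjusted p = 0.0135). gata5.S was at 4.88 ± 0.08 (SD, n = 3) with wnt3a+chordin and 5.01 ± 0.12 with kctd15 added. dlx5.L (6L, 33882698 to 33887832) was higher in the arrays labelled kctd15 alone and lower in those labelled kctd15 with wnt3a and chordin, a difference of -2.70 (SE 0.30, adjusted p = 0.00456). apln.L, the peptide ligand apelin (8L, 43788291 to 43804666), had a difference of 4.16 (SE 0.41, adjusted p = 0.00219). All 22 named genes past the threshold had 1 sign in 3 of 3 replicate differences.

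Further positive differences were nodal3.1.L (5.23), bcam.L (4.46), nkx2-3.S (4.28) and gfi1b.L, a repressor in blood cells (4.05), and further negative ones were dlx6.L (-4.72), pck1.L (-4.66), crisp1.5.S (-4.48) and klf2.S (-3.97). Endoderm genes had 2 of 18 lower, gata5.S and gata5.L (4 with the block and 6 adjusted over the list alone), and the list shifted down in 3 of 3 (median -0.67, camera, adjusted p = 0.000104; adjusted p = 0.345 with an estimated correlation) except with dim probe sets left out (0.451). Border genes had 3 of 20 lower, dlx6.L, dlx5.L and csrnp1.L (-1.42), and 4 adjusted over the list alone. The border list shifted down (median -0.74, replicate medians -0.59, -1.07 and 0.04, adjusted p = 0.00183; adjusted p = 0.530 with an estimated correlation), but not with all probe sets (0.0741). In the crest list sox9.L (-3.62, adjusted p = 0.0232) was lower among 21 (3 with the block and 3 adjusted over the list alone). Crest replicate medians were -1.96, -0.74 and 0.14, and the downward shift (median -1.03, adjusted p = 0.0197; adjusted p = 0.530 with an estimated correlation) was lost with the block (0.0933) and without lacZ replicate 1 (0.0552), kctd15 replicate 3 (0.0653), wnt3a+chordin replicate 1 (0.0621) or wnt3a+chordin+kctd15 replicate 1 (0.128). In the p53 list gadd45g.S (-1.63) was lower among 21 (2 adjusted over the list alone), with a downward shift in 3 of 3 (median -0.25, adjusted p = 0.0107; adjusted p = 0.483 with an estimated correlation) except without replicate 2 of wnt3a+chordin+kctd15 (0.0578).

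Posterior neural genes had meis3.L (1.84) and meis3.S (1.14) higher among 32 (3 adjusted over the list alone), with an upward shift in 3 of 3 (median 0.73, adjusted p = 0.000334; adjusted p = 0.530 with an estimated correlation). The ionocyte list shifted up in 3 of 3 (median 1.35, replicate medians 1.00, 2.68 and 0.38, adjusted p = 6.87e-09; adjusted p = 0.499 with an estimated correlation). Of its 27 members 0 passed in limma, 2 with the block and 4 adjusted over the list alone, and 11 were higher at an unadjusted p under 0.05; tekt3.L (2.50) had adjusted p = 0.0579, and 0.0474 with the block. The mesoderm list shifted up in 3 of 3 (median 0.41, adjusted p = 0.0288; adjusted p = 0.734 with an estimated correlation). Of its 30 members 0 passed in limma, 1 with the block and 1 adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05; the smallest p was that of foxc1.L (2.12, adjusted p = 0.0597). This call was lost with the muscle mean of each array as a covariate (0.0907) and without lacZ replicate 3 (0.611) or replicate 2 of wnt3a+chordin+kctd15 (0.407), where that mean was high. It was also lost without arrays where it was lower, kctd15 replicates 1 (0.0882) or 2 (0.0694) or wnt3a+chordin replicate 1 (0.421), and with dim probe sets left out (0.549). Wnt targets had nodal3.1.L higher among 32 (1 higher and 1 lower with the block, 4 higher and 2 lower adjusted over the list alone), with an upward shift in 3 of 3 (median 0.32, adjusted p = 0.0397; adjusted p = 0.530 with an estimated correlation) that was lost with the block (0.0504), without all arrays numbered 3 (0.178) and without single arrays (0.0541 to 0.261).

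By fry, of the 8 lists called, only the endoderm list passed; the border, crest, posterior, ionocyte, mesoderm, Wnt and p53 lists missed (adjusted p = 0.122, 0.178, 0.336, 0.187, 0.649, 0.260 and 0.083).

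No shift was called in the other 9 lists for the interaction. Under single alternatives the blood list shifted down with all probe sets (adjusted p = 0.00331), the pan-neural list up without lacZ replicate 1 (0.0258), and the BMP target list down with dim probe sets left out (0.0144) and without lacZ replicate 2 (0.026), wnt3a+chordin replicate 2 (0.0169) or wnt3a+chordin+kctd15 replicate 2 (0.00356). Pan-neural (median 0.09, adjusted p = 0.446), cement gland (0.50, 0.488), blood (-0.15, 0.152) and cell cycle genes (-0.15, 0.394) had 0 members past the threshold in limma, with 1 lower, 0, 2 lower, and 2 higher with 2 lower at an unadjusted p under 0.05. With the block 2 blood genes passed, of which runx1.L (-2.0, adjusted p = 0.0827) had 0.0378, and adjusted over the list alone 1 blood gene was lower and 0 of the other 3 lists passed. The members with the smallest p in the others were gmnn.L (-1.2, adjusted p = 0.203), agr2.L (0.51, 0.912) and ccna2.S (-0.70, 0.198). dll1.L (-2.43) was lower among 23 neuronal genes (2 higher and 1 lower with the block, 2 higher and 2 lower adjusted over the list alone, median 0.04, adjusted p = 0.654) and pitx3.S (-1.15) among 11 placode genes (1 adjusted over the list alone, median -0.03, 0.654). emx2.L (1.66) was higher among 21 anterior genes (1 adjusted over the list alone, median 0.04 and mean -0.05, adjusted p = 0.734). dlx3.L (-1.56) was lower among 23 epidermal genes (1 adjusted over the list alone), where the median (-0.16) and test pointed down and the mean (0.21) up (adjusted p = 0.913). Of 33 BMP targets tbx3.L (2.94) was higher and dlx5.L and dlx3.L lower (3 and 3 adjusted over the list alone, median -0.36, adjusted p = 0.095).

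In all, 371 of 32475 probe sets passed for the interaction (limma, adjusted p under 0.05), 230 positive and 141 negative, and 1063, including all 371, with the replicate block. Of 22 named genes 8 kept the call with each array left out, apln.L, gfi1b.L, nkx2-3.S, gata5.S, gata5.L, pck1.L, klf2.S and dlx5.L, and the other 14 had highest adjusted p from 0.051 to 0.12. The count was 134 without lacZ replicate 2, 144 without wnt3a+chordin replicate 3, 167 without kctd15 replicate 1 and 599 without kctd15 replicate 3. It was 189 without lacZ replicate 1, 187 without kctd15 replicate 2, 184, 197 and 198 without wnt3a+chordin replicates 1 and 2 and wnt3a+chordin+kctd15 replicate 1, 236 without its replicate 2, and 150, with 109 shared, without all arrays numbered 3.

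Differences between arrays labelled kctd15 and their controls in both settings were compared across probe sets, which are not independent replicates; the 2 comparisons share no array. Their fold changes correlated at Pearson's r of 0.285 and Spearman's rho of 0.190, with a covariance of 0.0519, and had an SD of 0.535 without and 0.341 with wnt3a and chordin. By replicate number r was 0.302, -0.001 and 0.357. Both comparisons called 16 probe sets higher, against 1.23 from independent calls, and 78 lower, against 7.07, and 6 in opposite directions. kctd15.L, tp63.L, tp63.S, cav1.L, ednra.S and ets1.L were lower in both. The 869 probe sets higher in the arrays labelled kctd15 alone had a median of 0.98 there and 0.15 with wnt3a and chordin, where 74.5% were above 0. The 1400 lower ones had medians of -1.19 and -0.15, and 68.9% were below 0 in the other setting. In the reverse direction, the 46 probe sets higher with wnt3a and chordin had a median of 1.38 there and 0.53 without them, where 82.6% were above 0. The 164 lower ones had -1.67 and -0.72, with 78.7% below 0. Each set was called in its own comparison, which draws its median there away from 0.

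**Figure D4:**
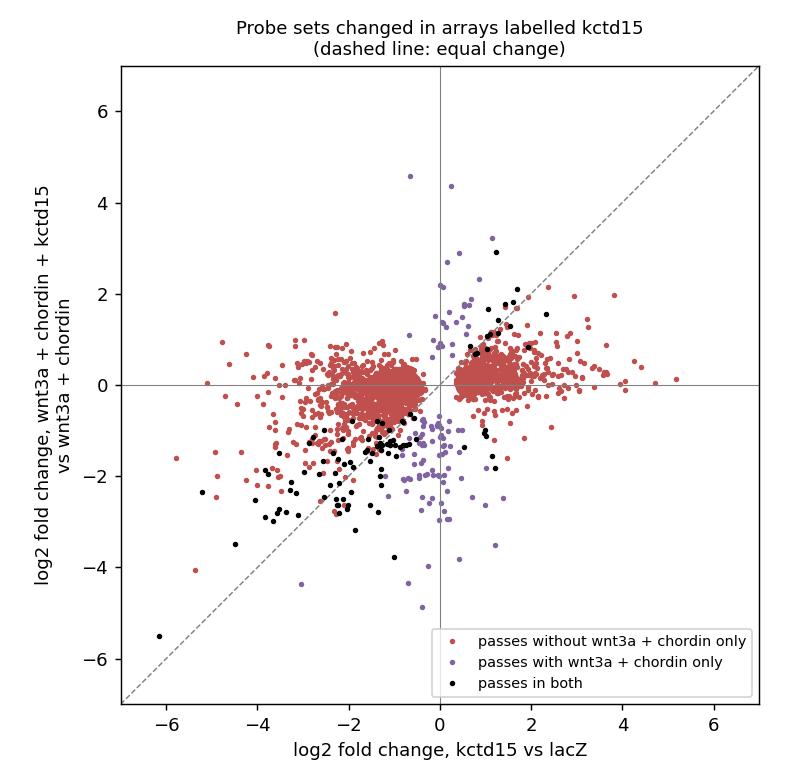
Log2 fold change of the arrays labelled kctd15 with wnt3a and chordin against that without them, 1 point per probe set past the threshold in either comparison or, in black, in both. Most points lie near 1 axis, as gata5.S does, at 5.17 without and 0.13 with wnt3a and chordin.

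A further comparison asked whether the genes that wnt3a and chordin had changed, such as foxd3.L and szl.L, moved back in the arrays labelled kctd15 as well. Between wnt3a+chordin+kctd15 and wnt3a+chordin foxd3.L differed by -2.39 (adjusted p = 0.234) and szl.L by 2.16 (0.839), against their direction before but short of the threshold. The neural crest list, of which wnt3a and chordin raised 17 of 21 members, shifted down by a median of -1.68 (adjusted p = 2.19e-14; adjusted p = 0.230 with an estimated correlation). Since both comparisons use the wnt3a+chordin arrays, the genes were chosen without 1 of these arrays and measured against it, in turn. The probe sets raised by wnt3a and chordin had a median of 0.02 (range -0.06 to 0.06 over the 3 arrays) and those lowered had 0.06 (-0.02 to 0.17). Measured without this step the medians were -0.00 and 0.07. They lay outside the values of 20 data sets simulated with no kctd15 effect, -0.02 (range -0.03 to -0.02) and 0.03 (0.02 to 0.03). Over the 3 arrays the medians of both whole sets varied more, on both sides of 0, so lying outside cannot show a kctd15 effect.

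Over all comparisons, 41 of 85 list tests were called by camera with its preset correlation, 23 up and 18 down. With an estimated correlation 0 of the 41 calls held (lowest adjusted p = 0.230, for the neural crest list in wnt3a+chordin+kctd15 against wnt3a+chordin). By that test 12 of the 85 had an unadjusted p under 0.05, and fry called 26 of the 41 in the same direction.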

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

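The tests on the kctd15 probe set and on muscle transcripts were chosen only after those results were seen; the tests of the smaller response with wnt3a and chordin and of other splits were set before.

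The difference between arrays labelled kctd15 and their controls was itself different with and without wnt3a and chordin, in the test of that difference, for 371 probe sets. Positive differences, with wnt3a and chordin minus without, were those of nodal3.1.L (5.23), bcam.L (4.46), nkx2-3.S (4.28), apln.L (4.16), gfi1b.L (4.05), tbx3.L (2.94), meis3.L (1.84), emx2.L (1.66) and meis3.S (1.14). Negative ones were those of gata5.S (-5.04), dlx6.L (-4.72), pck1.L (-4.66), crisp1.5.S (-4.48), klf2.S (-3.97), sox9.L (-3.62), gata5.L (-2.79), dlx5.L (-2.70), dll1.L (-2.43), gadd45g.S (-1.63), dlx3.L (-1.56), csrnp1.L (-1.42) and pitx3.S (-1.15). By list the difference was called upward for the ionocyte (adjusted p = 6.87e-09), posterior neural (0.000334), mesoderm (0.0288) and Wnt target lists (0.0397), and downward for the endoderm (0.000104), border (0.00183), p53 (0.0107) and crest lists (0.0197). With an estimated correlation 0 of these 8 list calls held, at adjusted p from 0.345 to 0.734, and fry called 1 of them. For the interaction, 4 of 100 splits drawn from the 200 possible within the settings gave as many probe sets, and the highest other split gave 1710 against the real 371. That share is under 0.05, but the count ignores the pairing of arrays by replicate number, so whether chance can be excluded stays open. The split with 1710 exchanged the labels of lacZ and kctd15 alone, which turns the difference into the sum of both, so the structure of the samples it points to is that of the groups themselves. It parts all 6 replicate pairs, as the real split does; of the 19 drawn splits that do so these were the only 2 with as many, and without the one fixed to be high the rest are too few for a share under 0.05.

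The comparisons of 2 groups allow 10 splits each, too few for a share under 0.05. In each of them 1 of 10 splits, the real one, gave as many probe sets. The real counts were 2269 for kctd15 against lacZ, 13421 for wnt3a+chordin against lacZ, 210 for wnt3a+chordin+kctd15 against wnt3a+chordin and 13619 for wnt3a+chordin+kctd15 against lacZ, and the highest other splits gave 2, 0, 17 and 0. Of the 10 splits 4 part all 3 replicate pairs, and the highest of the other 3 gave 0.

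The kctd15.L probe set was lower in all 6 arrays labelled kctd15. An exchange of the labels with and without kctd15 might show in the lac operon reporter, which was 8.99 higher in wnt3a+chordin than in wnt3a+chordin+kctd15, but how much lacZ mRNA each group received is not given. The crest list was lower in the arrays labelled kctd15 with wnt3a and chordin (median -1.68), the direction expected of a protein that restricts crest, but that action is what the arrays were made to examine, so exchanged and correct labels cannot be told apart. Another candidate explanation is that the probes lie outside the injected kctd15 mRNA, so that only the embryo's own transcript was read and would have had to be lower there: the highest level in the 6 arrays labelled kctd15 was 6.77, against a lowest of 10.22 in the others, and since the place of the probes in the mRNA is not given this stays open too. A fall of the embryo's own transcript in response to kctd15 mRNA is a biological hypothesis that was not tested.

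Muscle and axial mesoderm transcripts were high in some arrays of each group. Induction by wnt3a and chordin does not account for lacZ replicate 3, where the muscle members lay a median of 2.70 above wnt3a+chordin replicate 1. Carry-over of wnt3a mRNA into lacZ replicate 3 is argued against by wnt3a.S, 0.79 above the other lacZ arrays' mean (6.86 by injection). That of chordin mRNA stays open: chrd.1.S was 5.43 higher there. Mesodermal cells in some explants remain an untested candidate. The 14 of 19 muscle members more than 1 log2 unit higher in lacZ replicate 3 are the pattern itself. The labels name no step that removes such cells. Whether the embryos differed is open, as the labels give no batch.

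Fewer probe sets changed between arrays labelled kctd15 and their controls with wnt3a and chordin than without. A larger spread there is argued against by the ratio of the median residual SDs, 1.05 (0.213 against 0.203). Genes already at their changed level could account for it only if genes with free range still responded, but in 694 called probe sets that wnt3a and chordin left within 0.5 of lacZ the median change was 15.1% of that without them (0.136 against 0.896). Less kctd15 mRNA taken up may still be a cause: the interaction of kctd15.L was 0.66 (adjusted p = 0.942), but whether that probe set reads the injected mRNA is unknown, so the amounts cannot be told apart. A biological difference in the response of neural and epidermal cells stays open and was not tested.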

How the results depend on the processing

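Leaving out all arrays numbered 3, the muscle covariate and leaving out arrays for lists, named and injected genes were tests chosen after the data were seen. Of 59 alternatives for the counts 42 moved them by less than 1.5 times (17 moved more), and of 36 that left out 1 array 18 did. Under the alternatives run no call turned into one in the other direction, but 2 lists not called turned direction and were called: mesoderm, downward, in wnt3a+chordin+kctd15 against wnt3a+chordin without wnt3a+chordin replicate 1 (adjusted p = 0.0263) or wnt3a+chordin+kctd15 replicate 2 (0.0172), and pan-neural, upward, in kctd15 against lacZ without lacZ replicate 3 (0.00246). With the replicate block the counts rose to 4992 (kctd15 against lacZ), 443 (wnt3a+chordin+kctd15 against wnt3a+chordin) and 1063 (interaction). It made 2 named genes and 3 lists weaker and 5 genes stronger, each given with its result, made chrd.1.S stronger in wnt3a+chordin against lacZ (3.95, adjusted p = 0.0293) and wnt3a+chordin+kctd15 against lacZ (3.87, 0.0315), and changed no other call of a list or of a named or injected gene. One probe set per gene, by construction with fewer tested, gave 873, 5125, 88, 5215 and 168 (the order is kctd15 and wnt3a+chordin against lacZ, wnt3a+chordin+kctd15 against wnt3a+chordin and lacZ, and the interaction). Adjusted p under 0.01, a stricter threshold, gave 967, 46 and 72 for the first, the third and the interaction, and dim probe sets left out, again fewer tested, gave 136 and 202 for the last 2 of these. Only the arrays of the groups compared, which has fewer arrays, gave 49 for wnt3a+chordin+kctd15 against wnt3a+chordin. Without all arrays numbered 3 the first, the third and the interaction gave 1379, 6 and 150. With the muscle covariate they gave 2628, 273 and 372, so adjusting for the muscle mean did not lower them; whether fewer arrays are the cause was not tested.

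With 1 array left out the counts ran from 1312 to 2364, 11230 to 12538, 67 to 200, 11548 to 12763 and 134 to 599, and the list calls from 37 to 46 against 41. With an estimated correlation 0 list tests were called, and 26 by fry. Of 294 list tests with an array left out 263 kept the call and 31 were weaker, and of 1734 named gene tests 1409 kept their side, 320 were weaker and 5 stronger. Under quantile normalization all 41 list calls and 258 of 261 named gene tests held, except ventx1.1.S (0.0611), spib.L (0.0549) and nodal3.1.L (0.0501). For injected genes the range was 2.97 to 5.76 for chrd.1.S in wnt3a+chordin against lacZ, 2.89 to 5.68 in wnt3a+chordin+kctd15 against lacZ, -6.31 to -4.68 for kctd15.L in wnt3a+chordin+kctd15 against wnt3a+chordin (adjusted p = 0.0698, 0.0659 and 0.0512 without wnt3a+chordin replicates 1 and 3 and wnt3a+chordin+kctd15 replicate 3) and -1.67 to -0.97 for wnt3a.S in kctd15 against lacZ (passing at 0.0368 without lacZ replicate 1); the cause was not tested. The correlation of both differences labelled kctd15 ran from 0.201 to 0.366 without 1 replicate number. Centring each array on its median moved the median of all probe sets to 0.16 in wnt3a+chordin against lacZ and to -0.11 in the interaction. With dim probe sets left out 7 of 41 list calls were lost.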

Other observations

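The families below were chosen after the data were seen, and so were their tests: genes were grouped by the stem of their symbol, in 213 stems of at least 8 genes, and camera called 86 of 1065 tests, of which 0 held with an estimated correlation. In wnt3a+chordin against lacZ, all 14 cfap genes of cilia (median -3.01, adjusted p = 2.13e-08; adjusted p = 0.577 with an estimated correlation), such as cfap52.S (-6.63), and all 11 ift genes of transport in cilia (median -1.73, adjusted p = 2.79e-06; adjusted p = 0.577 with an estimated correlation) were lower, as were 16 of 22 cep genes of centrosomes (median -1.49, adjusted p = 6.54e-07; adjusted p = 0.577 with an estimated correlation), against 2 higher. Higher were 11 of 14 mcm genes of replication (median 1.14, adjusted p = 0.00902; adjusted p = 0.626 with an estimated correlation), with mcm4.S at 2.53, and all 10 utp genes of ribosome assembly (median 0.85, adjusted p = 0.00155; adjusted p = 0.642 with an estimated correlation). So were 18 of 24 polr genes of RNA polymerases (median 0.74, adjusted p = 0.00152; adjusted p = 0.577 with an estimated correlation), against 1 lower, and 11 of 12 psma genes of the proteasome (median 0.68, adjusted p = 0.00563; adjusted p = 0.587 with an estimated correlation).

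In the arrays labelled kctd15 without wnt3a and chordin, 5 of 10 gata genes were higher than in lacZ (median 2.27, adjusted p = 0.000153; adjusted p = 0.577 with an estimated correlation), and so were 3 of 8 socs genes, which dampen cytokine signals (median 1.19, adjusted p = 0.0157; adjusted p = 0.577 with an estimated correlation). The socs genes were socs1.S (1.47), socs2.S (1.33) and socs1.L (1.22). Lower there were 5 of 22 cep genes (median -0.42, adjusted p = 2.79e-06; adjusted p = 0.577 with an estimated correlation), 2 of 11 ift genes (median -0.65, adjusted p = 4.06e-05; adjusted p = 0.585 with an estimated correlation) and 2 of 14 cfap genes (median -0.77, adjusted p = 0.00107; adjusted p = 0.685 with an estimated correlation, and 0.101 by fry). Calpain protease genes were lower, 4 of 14 (median -0.93, adjusted p = 5e-04; adjusted p = 0.577 with an estimated correlation), with capn10l.L at -2.85 and capn2.L at -2.41, and so were 3 of 10 semaphorin genes (median -0.53, adjusted p = 0.00875; adjusted p = 0.577 with an estimated correlation), with sema5b.S at -2.26 and sema6d.L at -2.10.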
